A study of Mus musculus with 8 samples.

How the data were processed

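The 8 samples were of subcutaneous preadipocytes from Dicer lox/lox mice, 4 given the GFP adenovirus (control) and 4 given the Cre and GFP adenovirus (Dicer knockout). The labels call the samples of a group biological replicates and number them 1 to 4, without naming separate animals or cultures, so that p-values measure the spread between these samples. Per the submitters' processing notes, the arrays were processed with Affymetrix GCOS 1.3 and MAS5. The deposited values are linear array intensity (signal) per probe set. Their 2% trimmed mean was 1500 on every array, as computed from the values, so they had been scaled per array before they were deposited. Normalization beyond this scaling is not given in the sources used here.

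From these values everything else was computed with R 4.3.3 and limma 3.58.1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Values were taken as log2(signal + 73.1), where 73.1 is the 20th percentile of all values of the 8 arrays, so that fold changes of dim probe sets are understated. Of 45101 probe sets, the 64 array controls were left out, and the 27026 probe sets in the upper 60% by mean log2 value were tested. Probe sets were named from the platform annotation, which gave 1 symbol for 34945, several for 932 and none for 9160 of the non-control probe sets; a comparison with a RefSeq gene table by gene ID changed 0 symbols. No gene was named from a probe set with several symbols or none. A gene is represented by its brightest tested probe set with 1 symbol, which gave 13259 genes. Among the genes named here, Mov10, Ctsl, Plagl1, Rian and Ndn each had 1 tested probe set with a difference in the opposite direction, and in 0 of them did it reach an unadjusted p of 0.05. Coordinates are not printed because the annotation names no genome build.

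Knockout was compared with control by lmFit and eBayes with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Values in the text are mean signals with SD over 4 arrays, and log2 differences, knockout minus control, with the standard error of the fit. Single measures were compared by exact two-sided permutation of 4 against 4 arrays, whose smallest possible p is 0.0286.

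The labels share replicate numbers between the groups. Deviations from the group means correlated across probe sets at 0.341, 0.189, 0.199 and 0.372 between same-numbered control and knockout arrays 1 to 4, whereas arrays with different numbers gave -0.347 to 0.149. By the rule that every same-numbered pair exceeds 0.1, the numbers were taken to pair the samples. Some arrays with different numbers, both odd or both even, exceeded 0.1 too (0.149, 0.134 and 0.117). The rule alone thus does not tell pairing from a likeness among odd-numbered or even-numbered samples. Among the arrays of the other group, each array still correlated most with its same-numbered partner. Arrays of the same group were not compared in this check. Without centring on the group means, both arrays numbered 1, 2 and 4 had the same highest correlation (0.9694, 0.9684 and 0.9674). That of knockout 3 (0.9656) was above that of control 3 (0.9645), so knockout 3 was closest to another array. The pairing comes from the labels' numbers and from this check of the data, since the labels do not say what a number stands for. The unpaired fit, set as the main design before the data were examined, was kept, and the fit with the replicate number as a block is called the paired fit.

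Before the data were examined, 29 gene lists were fixed: microRNA pathway, let-7 targets, microRNA host and imprinted genes, miR-29 targets, miR-21 targets, p53 targets, G1/S and DNA replication, G2/M and mitosis, senescence and secretory phenotype, antioxidant and NRF2 response, unfolded protein response, interferon-stimulated genes, extracellular matrix, contractile and smooth muscle, adipocyte differentiation, preadipocyte and progenitor, brown fat and thermogenic, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, lysosome, apoptosis, ribosomal proteins, and markers of macrophages and leukocytes, endothelium, pericytes, skeletal muscle, keratinocytes and epithelium, and Schwann and neural cells. The target lists hold well-known targets from memory, not predictions. All 29 had at least 5 tested members and were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the lists. With the preset correlation 8 lists passed in the unpaired fit and 9 in the paired fit. With an estimated correlation 0 lists passed in either fit, with smallest adjusted p of 0.358 and 0.286. By fry, which tests whether a list's genes move on balance in the same direction, 0 lists passed, with smallest adjusted p of 0.348 unpaired and 0.0884 paired, and 0 passed by its test of change in either direction, with a smallest adjusted p of 0.131. Some genes are on more than 1 list, such as Btg2 (p53 and miR-21 targets), Cxcl10 (senescence and interferon), Perp (p53 targets and keratinocyte markers), Thbs1 (let-7 targets and matrix) and Dlk1 (imprinted and preadipocyte).

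The rule for named genes, also fixed beforehand, took all Dicer1 probe sets, up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold without overlap between groups, and up to 4 tested members with the smallest p in each list. Genes outside it are said to be named after their values were seen. A planned test of microRNA seed matches in 3′ untranslated regions needs transcript sequences, which were not used here, and it was not run.

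The scripts were tested on simulated data for this comparison. In 5 runs on 27026 probe sets with 200 changed in each, the unpaired fit recovered 5.08%, 32.2% and 80.3% of changes of 1.5, 2 and 4 times, and the paired fit 15.5%, 43.3% and 80.9%; false calls were 0.256% and 1.49% of all calls. On 13259 genes, camera recovered 50 of 50 lists of 25 genes shifted by 0.2 on the log2 scale and called 1 of 240 unshifted lists; residuals were drawn independently for each gene, so correlation between genes beyond the replicate pairs was not simulated. The alternatives tried were other pseudocounts, filters, normalizations, variance models and array weights, the paired fit, averaging the probe sets of a gene, an estimated correlation, and leaving out each array. The number of arrays, 4 in each group, limits the precision.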

Results

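Preadipocytes, the fibroblast-like precursors of fat cells, were taken from the subcutaneous fat of day 2 newborn C57BL/6 mice with floxed alleles of Dicer, the ribonuclease that cuts microRNA precursors into mature microRNAs. The cells received adenovirus at 750 MOI with 4 µg/mL polybrene. The virus encoded GFP in 4 control samples and GFP together with Cre recombinase, which excises the floxed segment, in 4 Dicer knockout samples. Total RNA collected 4 days after infection was hybridised to Affymetrix arrays, 1 array per sample. The comparison asks which transcripts differ after the virus meant to delete Dicer. As 0 arrays are of Cre virus in cells without floxed Dicer, effects of Cre or its virus cannot be told apart from Dicer loss. This holds for every difference between the groups given below. Each array gave a signal for 45101 probe sets, and 27026 of these, which stand for 13259 genes, entered the tests. The median signal was between 321.1 and 418.9 on the 8 arrays. Across probe sets, the correlation between any array and its closest neighbour was 0.9645 to 0.9694. The number of arrays limits the precision. Same-numbered control and knockout arrays deviated together, so values from a paired fit, with the replicate number as a block, are given where they change a call. The odd-numbered replicates of both groups also stood apart from the even-numbered ones, a split that crosses the groups evenly. The 18S ribosomal RNA 5′ probe set read 5905.9 to 14007.2 in the former and 30583.9 to 43029.9 in the latter.

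The Dicer1 transcript was measured by 2 probe sets, and neither differed between the groups by more than the spread between arrays. The brighter (1460571_at) read 1152.7, 1140.7, 2113.7 and 1190.3 on control arrays 1 to 4 and 1158.3, 1190.4, 1403.8 and 1110.1 on knockout arrays 1 to 4, a log2 difference of -0.15 (SE 0.20, limma adjusted p = 0.999, exact two-sided permutation p = 0.714). Without control array 3 the difference was 0.0572, in the opposite direction. The dimmer (1427941_at) read 737 ± 289 (SD, n = 4) in controls and 577 ± 123 (SD, n = 4) in knockouts, a log2 difference of -0.26 (SE 0.27, limma adjusted p = 0.999). For this probe set the difference was -0.499 without control array 4 and -0.0758 without control array 3. A probe set outside the excised segment does not check the deletion, and where these 2 lie relative to that segment is not given in the sources used here. Of the 19 tested members of the microRNA pathway list, 13 had a log2 difference above 0, and the list mean was 0.0875 with all 4 replicate pairs above 0. The list did not pass camera's test with the preset correlation in the unpaired fit (adjusted p = 0.103) and passed in the paired fit (adjusted p = 0.0382; adjusted p = 0.347 there with an estimated correlation). The paired call was lost without pair 1 (adjusted p = 0.0769), pair 2 (0.0632) or pair 3 (0.0722). The unpaired fit called the list with the upper 40% of probe sets (list mean 0.104, adjusted p = 0.043) and without control 1 (0.108, 0.0392), knockout 2 (0.107, 0.0418) or knockout 4 (0.142, 0.009), while its mean fell to 0.0515 without control 4, 0.0569 without knockout 1 and 0.0434 without knockout 3. It was 0.113 in the odd-numbered and 0.0618 in the even-numbered pairs. No member passed on its own, over all genes or adjusted over the list alone, in either fit. Tarbp2, a double-stranded RNA binding partner of Dicer, read 2060 ± 155 in controls and 2825 ± 478 in knockouts (SD, n = 4 each; log2 difference 0.43, SE 0.14, limma adjusted p = 0.999). Mov10, an RNA helicase, had a log2 difference of 0.37 (SE 0.17). Tnrc6b and Tnrc6a, which link Argonaute proteins to deadenylation, had log2 differences of 0.34 (SE 0.20) and 0.32 (SE 0.22).

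Hmga2, a chromatin protein of growing embryonic cells and a classic let-7 target, gave the only change past the threshold in the unpaired fit. Its probe set 1450781_at rose 2.59-fold, from 3016 ± 693 in controls to 7800 ± 619 in knockouts (SD, n = 4 each; log2 difference 1.37, SE 0.16, limma adjusted p = 0.0335), and the lowest knockout array lay above the highest control array. The brightest Hmga2 probe set (1450780_s_at), which stands for the gene in gene counts, read 6095 ± 1087 and 12730 ± 2184 (SD, n = 4 each; log2 difference 1.06, SE 0.16, limma adjusted p = 0.283), so the count of changed genes was 0 higher and 0 lower. Another Hmga2 probe set, 1422851_at, had a log2 difference of 0.86 (SE 0.23). The adjusted p of 1450781_at rose above 0.05 when control array 2 or 3 or any of the 4 knockout arrays was left out. It was 0.102 without control 2, 0.259 without control 3, and 0.103, 0.258, 0.259 and 0.131 without knockout 1, 2, 3 and 4. It also rose above 0.05 with no filter on low values (0.063), with median centring (0.0778) and without the mean-variance trend (0.539). The log2 difference itself stayed between 1.25 and 1.49. In all, 1 probe set passed as higher and 0 as lower. The unadjusted limma p was under 0.05 for 1019 probe sets, 3.77% of those tested, and in 664, or 2.46%, all knockout values lay on the same side of all control values, against 2.86% by chance.

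The paired fit called 10 probe sets higher and 3 lower, or 8 genes higher and 2 lower, with 2470 probe sets (9.14%) at an unadjusted p under 0.05. Both of the brighter Hmga2 probe sets were among them. Rsad2, an interferon-induced antiviral enzyme, was called by 2 probe sets (log2 differences 0.78 and 0.86, paired adjusted p = 0.0165 for each). The chemokines Ccl5 (2.04-fold, paired SE 0.12 on the log2 scale, paired adjusted p = 0.0165) and Cxcl10 (1.57-fold, paired adjusted p = 0.0498) were called higher. Dlk1, the preadipocyte factor that restrains adipogenesis, read 48650 ± 19280 in controls and 31350 ± 19680 in knockouts (SD, n = 4 each) and was called lower (log2 difference -0.72, paired SE 0.11, limma paired adjusted p = 0.0436). Plagl1, an imprinted zinc finger gene, was called lower too (log2 difference -0.51, paired adjusted p = 0.0336). The remaining calls, named after their values were seen, were C1qtnf3 (2.28-fold), Tmed5 (1.64-fold), Anxa8 (1.63-fold) and Ptprv (1.51-fold) higher, and the probe set 1418271_at, with no gene symbol here, lower (log2 difference -0.96). Leaving out single arrays in the unpaired fit moved some of these log2 differences. For Dlk1 this gave -1.1 without knockout 1 and -0.451 without knockout 4. For Plagl1 it gave -0.207 without control 1, -0.816 without knockout 1 and -0.265 without knockout 4. For Anxa8 it gave 0.41, 1.07 and 0.47 without these same arrays, and for Ptprv 0.36 without control 1. A single left-out array leaves its partner unmatched, so these shifts take in differences between replicate numbers. Dlk1 and Plagl1 were lower, and Anxa8 and Ptprv higher, in 4 of 4 pairs. The counts of the paired fit moved with the pairs entered. Without pair 1 they were 45 higher and 35 lower, without pair 2 they were 1 and 0, without pair 3 they were 0 and 0, and without pair 4 they were 2 and 0.

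**Figure D1:**
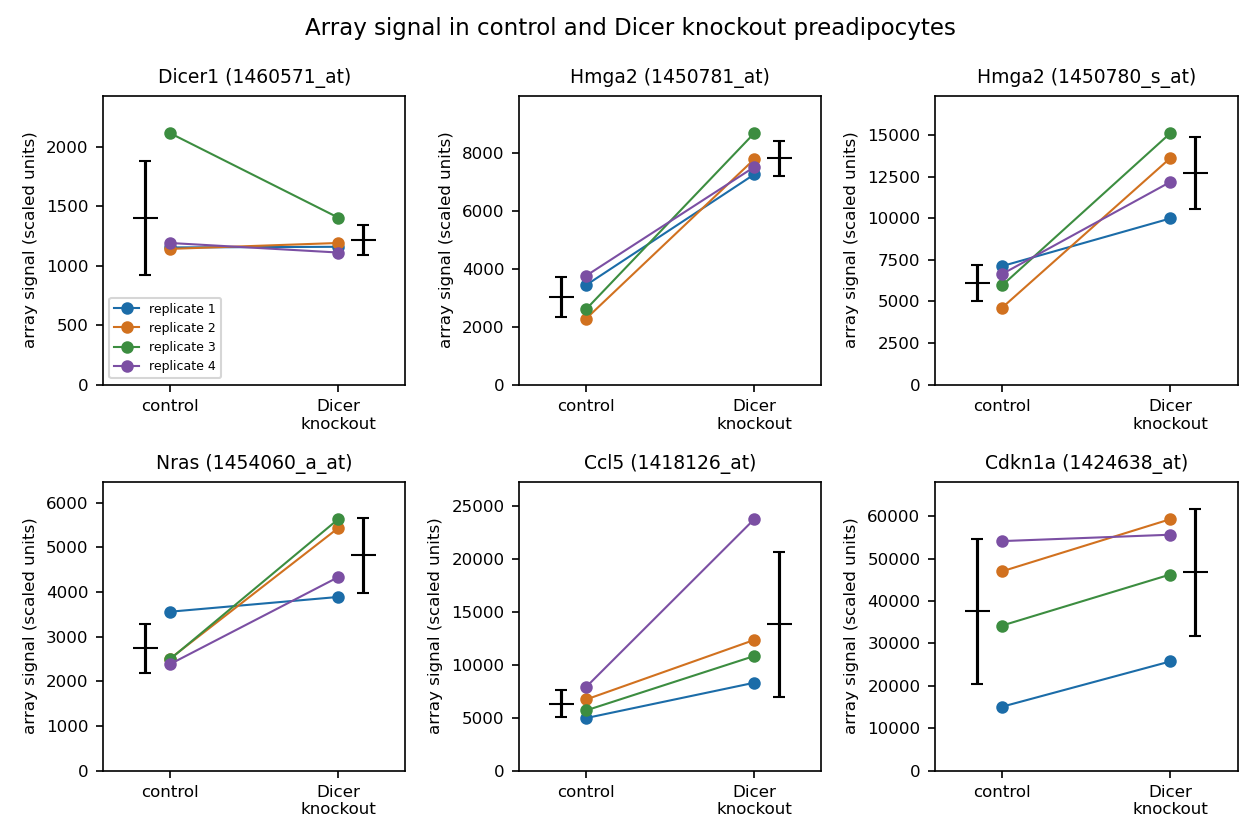
Array signal (vertical axis, scaled units, from 0) of Dicer1, both brighter Hmga2 probe sets, Nras, Ccl5 and Cdkn1a in control and Dicer knockout preadipocytes; each coloured line joins the control and knockout arrays with the same replicate number, and black marks give the mean and SD of 4 arrays. The knockout arrays of Hmga2 1450781_at sit at 7250.8 to 8671.9, above the control arrays at 2274.8 to 3755.2, while control array 3 of Dicer1 lies at 2113.7 and the other controls at 1140.7 to 1190.3.

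Messenger RNAs known as let-7 targets were higher as a list in the knockout. The mean log2 difference over its 24 tested members was 0.13, with 15 above 0 and all 4 replicate pairs above 0 (camera with the preset correlation, adjusted p = 0.00518; adjusted p = 0.476 with an estimated correlation). The mean was 0.0581 in the odd-numbered and 0.2 in the even-numbered pairs. No member passed over all genes in the unpaired fit and 1, Hmga2, in the paired fit. In the unpaired fit 2 members, Hmga2 and Nras, passed as higher adjusted over the list alone, and 6 did in the paired fit. Nras, a small GTPase, read 2736 ± 550 in controls and 4820 ± 844 in knockouts (SD, n = 4 each; log2 difference 0.80, SE 0.16). Ccnd2, a G1 cyclin, and Thbs1, a secreted inhibitor of vessel growth, had log2 differences of 0.41 (SE 0.14) and 0.48 (SE 0.19). The list mean was 0.0564 without Hmga2 and Nras (adjusted p = 0.121), a selection of large rises made after their values were seen, and 0.0777 without control array 4 (adjusted p = 0.131), so the call was lost in both cases.

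Among the other microRNA target lists, the 19 tested miR-21 targets had a mean log2 difference of 0.14, with 13 above 0 and all 4 pairs above 0 (camera with the preset correlation, adjusted p = 0.0245; adjusted p = 0.69 with an estimated correlation). Odd-numbered pairs gave 0.092 and even-numbered pairs 0.185. No member passed over all genes in either fit or adjusted over the list alone in the unpaired fit. Adjusted over the list alone in the paired fit, Skp2 and Btg2 passed as higher and Tgfbi, named after its values were seen, as lower. Skp2, a ubiquitin ligase subunit, had a log2 difference of 0.39 (SE 0.14), Reck, an inhibitor of matrix metalloproteinases, 0.35 (SE 0.15) and Spry2, an inhibitor of growth factor signalling, 0.35 (SE 0.17). The miR-21 call was lost without control 2 (list mean 0.124, adjusted p = 0.115), control 4 (0.0828, 0.295), knockout 1 (0.14, 0.051), knockout 2 (0.106, 0.0984) or knockout 3 (0.0977, 0.16), and with no filter on low values (0.108, 0.0814), whereas the mean was 0.21 without knockout 4. The 24 tested miR-29 targets, mostly collagens and other matrix genes, did not pass (mean log2 difference 0.0533, 2 of 4 pairs above 0, adjusted p = 0.474, 0 members adjusted over the list alone). Col5a1 and Col15a1 had log2 differences of 0.29 (SE 0.18) and -0.33 (SE 0.21).

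Targets of p53, the transcription factor induced by DNA damage and other stress, were higher as a list. Over its 34 tested members the mean log2 difference was 0.20, with 29 members and all 4 replicate pairs above 0 (camera with the preset correlation, adjusted p = 0.000361; adjusted p = 0.69 with an estimated correlation). The pairs gave 0.128, 0.226, 0.314 and 0.133, and the means were 0.221 in the odd-numbered and 0.18 in the even-numbered pairs. No member passed over all genes in either fit. Adjusted over the list alone, 0 members passed in the unpaired fit, whereas 14 passed as higher, 1 as lower and 19 in neither direction in the paired fit. The member called lower was Gadd45a (log2 difference -0.50), named after its values were seen. Perp, a desmosomal protein, read 247 ± 149 in controls and 461 ± 101 in knockouts (SD, n = 4 each; log2 difference 0.82, SE 0.31). The death receptor Fas, the metabolic regulator Tigar and the antiproliferative gene Btg2 had log2 differences of 0.41 (SE 0.17), 0.44 (SE 0.18) and 0.49 (SE 0.25). Among the 14 members called higher there, and named after their values were seen, Cdkn1a had a log2 difference of 0.39 (SE 0.36, paired SE 0.10), Mdm2 0.40 (SE 0.28, paired SE 0.08), Ccng1 0.36 (SE 0.20, paired SE 0.09) and Eda2r 0.47 (SE 0.29, paired SE 0.10). Each was higher in 4 of 4 pairs. Without control array 1 the list mean was 0.0867 (adjusted p = 0.0608), so that the call of the unpaired fit was lost, and without knockout array 1 it was 0.338. Without control array 1 the unpaired log2 difference was 0.00649 for Cdkn1a, 0.164 for Mdm2, 0.252 for Eda2r, 0.241 for Btg2 and 0.286 for Tigar. That leaves knockout array 1, also low on this list, unmatched, so these values do not show that the members rest on control array 1. Without both arrays of pair 1 the paired fit gave a list mean of 0.224 and kept its call with the preset correlation.

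The cell cycle lists did not pass. The 34 tested genes of G1/S and DNA replication had a mean log2 difference of -0.0489 (adjusted p = 0.121) and the 35 of G2/M and mitosis one of 0.0404 (adjusted p = 0.246), with 0 members of either list past the threshold over all genes or adjusted over the list alone in both fits. Leaving out an array put the first past the threshold without control 3 (-0.0827, adjusted p = 0.0144) or knockout 4 (-0.0883, 0.009), and the second without control 1 (0.0977, 0.00232) or knockout 2 (0.078, 0.0294). Uhrf1 and Tk1, both needed in S phase, had log2 differences of -0.30 (SE 0.15) and -0.23 (SE 0.12), and Ccna2, a cyclin of S and G2 phase, 0.24 (SE 0.13). The 28 tested apoptosis genes had a list mean of 0.0362 (adjusted p = 0.474, 0 members adjusted over the list alone in both fits).

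In the list of senescence and secretory genes, the unpaired fit called Cxcl10, Ccl5 and Ccl7 higher adjusted over the list alone, and 0 members passed over all genes. In the paired fit 2 members, Ccl5 and Cxcl10, passed over all genes, and 6 passed as higher and 5 as lower adjusted over the list alone. Cxcl10 read 10420 ± 899 in controls and 16490 ± 2820 in knockouts (SD, n = 4 each; log2 difference 0.65, SE 0.13). Ccl5 read 6307 ± 1278 and 13790 ± 6833 (SD, n = 4 each; log2 difference 1.03, SE 0.26). Ccl7 and Ccl2, which attract monocytes, had log2 differences of 0.59 (SE 0.16) and 0.60 (SE 0.18). Cdkn2a, the senescence-linked cell cycle inhibitor locus, looked up after the list had been tested, had a log2 difference of -0.20 (SE 0.12, paired SE 0.07). It was among the 5 members that passed as lower adjusted over the list alone in the paired fit (limma adjusted p = 0.0403). The list of 35 tested members did not pass (adjusted p = 0.645), and its mean of 0.0322 and median of -0.0384 differed in sign.

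Interferon-stimulated genes were higher as a list, with a mean log2 difference of 0.12 and 24 of 36 tested members above 0 (camera with the preset correlation, adjusted p = 0.0108; adjusted p = 0.72 with an estimated correlation). The replicate pairs differed, at 0.395, -0.00196, -0.0948 and 0.178 for pairs 1 to 4, or 0.15 in the odd-numbered and 0.0878 in the even-numbered ones. Adjusted over the list alone, 4 members passed as higher in the unpaired fit, Cxcl10, Rsad2, Ifit1 and Ifih1, and 0 passed over all genes; in the paired fit these counts were 7 and 2. Rsad2 read 4323 ± 858 in controls and 7629 ± 2145 in knockouts (SD, n = 4 each; log2 difference 0.78, SE 0.22). Ifit1, which binds foreign RNA, and Ifih1, a cytoplasmic sensor of double-stranded RNA, had log2 differences of 0.47 (SE 0.13) and 0.56 (SE 0.16). The list lost its call without control 1 (0.0407, adjusted p = 0.239), knockout 1 (0.105, 0.124) or knockout 4 (0.0463, 0.274), and with array weights (0.0766, 0.0926).

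Contractile and smooth muscle genes were higher as a list, with a mean log2 difference of 0.18 over 16 tested members, 15 of them and all 4 pairs above 0 (camera with the preset correlation, adjusted p = 0.000731; adjusted p = 0.358 with an estimated correlation). This list mean was also the only one of the 29 at the smallest p that the exact two-sided permutation of 4 against 4 arrays can give, 0.0286 (0.552 after Benjamini-Hochberg adjustment over the lists at best). For the other lists called in the unpaired fit that permutation gave p = 0.0571 (keratinocyte), 0.143 (let-7), 0.257 (miR-21), 0.314 (p53 and lysosome), 0.429 (interferon) and 0.457 (cholesterol). It does not use the pairing. For the contractile list, odd-numbered pairs gave 0.118 and even-numbered pairs 0.246. Adjusted over the list alone, 2 members passed as higher in either fit, Acta2 and Myl9, and 0 passed over all genes. Acta2, smooth muscle actin, read 18710 ± 3637 in controls and 29880 ± 4149 in knockouts (SD, n = 4 each; log2 difference 0.68, SE 0.15). The myosin light chain Myl9 read 6413 ± 426 and 8663 ± 779 (SD, n = 4 each; log2 difference 0.43, SE 0.11). The actins and actin-binding genes Actg2 and Tagln had log2 differences of 0.55 (SE 0.26) and 0.25 (SE 0.19). That of Tagln was 0.0814 without control 4 and 0.414 without control 1, in the unpaired fit with the partner array left unmatched. The 34 tested extracellular matrix genes did not pass (mean log2 difference -0.0249, adjusted p = 0.574, 0 members adjusted over the list alone), although the list passed without knockout 3 (-0.0988, adjusted p = 0.0115). In the paired fit, adjusted over the list alone, Thbs1 passed as higher and Mfap4 (log2 difference -0.53, SE 0.27) and Dcn (-0.39, SE 0.29), the latter named after its values were seen, as lower.

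**Figure D2:**
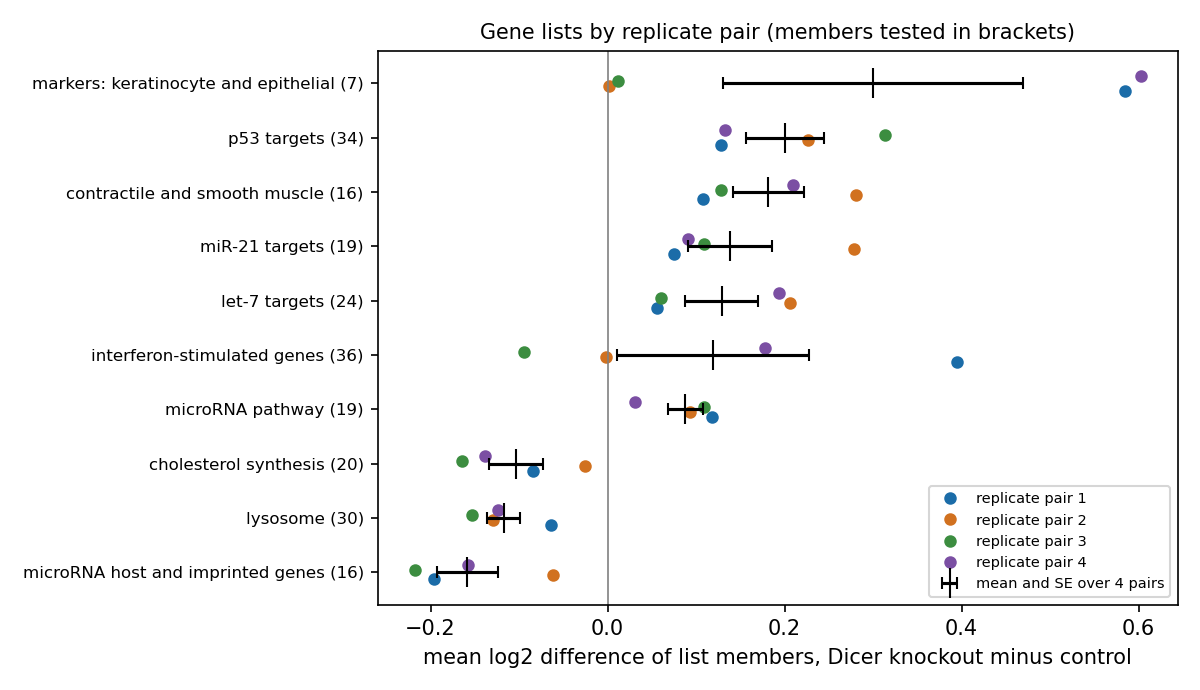
Mean log2 difference (horizontal axis, Dicer knockout minus control) of the members of the 10 gene lists past the threshold in the unpaired or paired fit with the preset correlation; coloured dots are the 4 replicate pairs, and the black mark is their mean with its SE. All 4 dots lie above 0 for the p53, contractile, let-7, miR-21, keratinocyte and microRNA pathway lists (for the keratinocyte list at only 0.0013 and 0.0115 in pairs 2 and 3), whereas those of the interferon list reach from -0.0948 to 0.395.

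Lysosomal genes were lower as a list, with a mean log2 difference of -0.12, 21 of 30 tested members below 0 and all 4 pairs below 0 (camera with the preset correlation, adjusted p = 0.000731; adjusted p = 0.72 with an estimated correlation). No member passed over all genes in either fit or adjusted over the list alone in the unpaired fit. In the paired fit 2, Ctsl and Gaa, passed as lower adjusted over the list alone. The protease cathepsin L (Ctsl) read 39990 ± 2618 in controls and 32080 ± 1843 in knockouts (SD, n = 4 each; log2 difference -0.32, SE 0.09). The glycogen-degrading enzyme Gaa had a log2 difference of -0.45 (SE 0.14). Atp6ap1, a proton pump subunit, and Ctsh, another cathepsin, had log2 differences of -0.26 (SE 0.10) and -0.33 (SE 0.16). The call was lost without control 4 (-0.0727, adjusted p = 0.136) or knockout 1 (-0.0573, 0.282), and the mean was -0.0716 without control 3 and -0.196 without control 1. It was -0.109 in the odd-numbered and -0.127 in the even-numbered pairs. Cholesterol synthesis genes were lower as well, with a mean of -0.10, 16 of 20 tested members below 0 and all 4 pairs below 0 (camera with the preset correlation, adjusted p = 0.0272; adjusted p = 0.788 with an estimated correlation). Of its members, 0 passed over all genes or adjusted over the list alone in either fit. Its 4 members with the smallest p, Nsdhl, Dhcr7, Tm7sf2 and Ebp, all sterol enzymes, had log2 differences of -0.23 (SE 0.11), -0.28 (SE 0.16), -0.26 (SE 0.16) and -0.16 (SE 0.11). That call was lost without control 1 (-0.0707, adjusted p = 0.32), control 3 (-0.0626, 0.192), control 4 (-0.0743, 0.258) or knockout 2 (-0.0273, 0.681), and with array weights (-0.0582, 0.34), whereas the mean was -0.205 without control 2. Odd-numbered pairs gave -0.125 and even-numbered pairs -0.0815.

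Other metabolic and stress lists did not pass, and their unpaired fits held 0 members past the threshold over all genes or adjusted over the list alone. The list means were -0.00514 for 40 oxidative phosphorylation genes (adjusted p = 0.863), -0.00109 for 29 glycolysis and hypoxia genes (0.678), -0.017 for 32 antioxidant genes of the NRF2 response (0.683), 0.0087 for 27 genes of the unfolded protein response (0.762) and -0.00558 for 30 ribosomal protein genes (0.537). For oxidative phosphorylation the median of 0.000947 lay above 0 while the mean and the test's direction lay below it. For glycolysis the median of 0.0135 and the test's direction lay above 0 and the mean below it. Adjusted over the list alone in the paired fit, 1 member each passed as lower: Ndrg1 among the glycolysis and hypoxia genes (log2 difference -0.52), Gsta4, a glutathione transferase, among the antioxidant genes (-0.61, SE 0.24), and Ppp1r15a, a phosphatase subunit that ends the integrated stress response, among the unfolded protein response genes (-0.58, SE 0.20).

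Genes of adipocyte differentiation did not pass as a list (mean log2 difference -0.094 over 24 tested members, 16 of them below 0, adjusted p = 0.121), and 0 members passed over all genes, or adjusted over the list alone in the unpaired fit. Klf15, a transcription factor of adipogenesis, read 589 ± 43.8 in controls and 297 ± 163 in knockouts (SD, n = 4 each; log2 difference -0.95, SE 0.30). Fatty acid synthase (Fasn) had a log2 difference of -0.40 (SE 0.22), the adipogenic factor Cebpa -0.26 (SE 0.16), and the fatty acid carrier Fabp4 0.55 (SE 0.34). Of these, Klf15 and Fasn passed as lower and Fabp4 as higher adjusted over the list alone in the paired fit. The 33 tested preadipocyte and progenitor genes did not pass either (mean log2 difference -0.00652 with the test's direction above 0, adjusted p = 0.792). Their members Wnt5a and Icam1 had log2 differences of 0.52 (SE 0.25) and 0.31 (SE 0.16). Adjusted over that list alone in the paired fit, Dlk1 passed as lower and Klf4 (log2 difference 0.33), named after its values were seen, as higher. The 12 tested brown fat genes had a mean of -0.0164, with a median of 0.00333 and a test direction above 0 (adjusted p = 0.955). Ppargc1a, a coactivator of mitochondrial and thermogenic genes, read 1119 ± 389 and 629 ± 245 (SD, n = 4 each; log2 difference -0.76, SE 0.29). It was the 1 member past the threshold adjusted over the list alone in the paired fit.

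Hosts of microRNAs and imprinted genes had a mean log2 difference of -0.16 over 16 tested members, with 11 members and all 4 pairs below 0. The list did not pass in the unpaired fit (adjusted p = 0.0826) and passed in the paired fit (adjusted p = 0.000919; adjusted p = 0.286 there with an estimated correlation). It passed in the unpaired fit when control 2 (-0.204, adjusted p = 0.0149), control 4 (-0.24, 0.0374) or knockout 1 (-0.257, 0.0122) was left out, whereas without control 1 its mean shrank to -0.0473 (adjusted p = 0.79) and without knockout 4 to -0.0769. Odd-numbered pairs gave -0.207 and even-numbered pairs -0.11. In the unpaired fit 0 members passed over all genes or adjusted over the list alone. In the paired fit Dlk1 and Plagl1 passed over all genes. There 5 passed as lower adjusted over the list alone, Dlk1, Plagl1, the growth inhibitor Cdkn1c (log2 difference -0.50, SE 0.33), the noncoding RNA Rian (-0.41, SE 0.23) and Ndn (-0.27, SE 0.20), and 1, Mest, as higher (0.50, SE 0.34). Ndn and Mest were named after their values were seen.

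Of the 6 lists of markers of other cell types, 1 passed in the unpaired fit and 0 in the paired fit. Keratinocyte and epithelial markers had a mean log2 difference of 0.30 with 7 of 7 tested members and all 4 pairs above 0 (camera with the preset correlation, adjusted p = 0.0245; adjusted p = 0.408 with an estimated correlation). Of its 16 members 7 were tested, and the 4 with the smallest p read 247, 1258, 252 and 280 in controls. Array medians were 321.1 to 418.9, so all of these but the one at 1258 were dim. The pairs gave 0.585, 0.0013, 0.0115 and 0.603, so the mean rests on pairs 1 and 4, 1 odd-numbered and 1 even-numbered (means of 0.298 and 0.302 over the odd and even pairs). The paired fit did not call the list (adjusted p = 0.0625). It holds Perp, which is also a p53 target, and without Perp the mean was 0.214 (adjusted p = 0.103). The call was also lost without control 1 (0.244, 0.0774), control 4 (0.211, 0.196) or knockout 1 (0.262, 0.124), with no filter on low values (0.0916, 0.391) and with array weights (0.218, 0.0926). Epcam, an epithelial adhesion molecule, read 1258 ± 163 and 1724 ± 379 (SD, n = 4 each; log2 difference 0.42, SE 0.18). Skeletal muscle markers had a mean of 0.25 over 8 tested members (adjusted p = 0.0826), with Acta1 at 0.53 (SE 0.19). They passed without control 2 (0.306, adjusted p = 0.0252) or control 3 (0.297, 0.0446), whereas their mean was 0.133 without control 1 (adjusted p = 0.528). Their 4 members with the smallest p read 508 (Acta1), 298, 258 and 336 in controls, so most of these were dim too. Schwann and neural markers had a mean of -0.18 over 6 members (adjusted p = 0.29), and macrophage and leukocyte markers one of 0.11 over 11 (adjusted p = 0.574). Endothelial markers had a mean of 0.0237 over 11, with the test's direction below 0 (adjusted p = 0.792), and pericyte markers 0.0257 over 7 (adjusted p = 0.831). Fcgr1, a macrophage Fc receptor, had a log2 difference of 0.87 (SE 0.33) at a dim signal of 189 ± 111 and 370 ± 32.5 (SD, n = 4 each). The endothelial gene Egfl7 had one of -0.46 (SE 0.15) and the pericyte marker Anpep one of -0.55 (SE 0.30). No member of a marker list passed over all genes in either fit or adjusted over the list alone in the unpaired fit. In the paired fit Anpep passed as lower adjusted over the list alone.

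Compared without the pairing, no difference between the groups was detected in the array controls. The log2 ratio of 3′ to 5′ signal was 0.021 ± 0.109 in controls and -0.010 ± 0.042 in knockouts for Gapdh (SD, n = 4 each; exact two-sided permutation p = 0.771), and 0.915 ± 0.133 and 0.904 ± 0.076 for Actb (SD, n = 4 each; exact permutation p = 0.886). The Cre hybridization control, a bacteriophage transcript spiked onto every array, comes from the recombinase gene that the knockout virus also carries, so viral RNA can add to its signal. It had a log2 ratio to the BioD, BioC and BioB spike-ins that was 0.045, 0.039 and 0.038 higher on the knockout arrays (exact permutation p = 0.343, 0.343 and 0.629). The log2 signal of the 18S ribosomal RNA 5′ probe set was 0.43 higher in knockouts (exact permutation p = 0.6). This permutation does not use the pairing. Each knockout array read above its same-numbered control (14007.2 against 11355.6, 42617.5 against 30583.9, 9524.9 against 5905.9 and 43029.9 against 36375.2). The 18S M probe set was likewise higher in the knockout of every pair. No other measure here differed in the same direction in every pair. After Benjamini-Hochberg adjustment over the 6 measures tested by permutation every p was 0.886.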

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

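In 14 of the 224 sets of 4 arrays examined, for the named genes, the lists and the array controls, a single array lay far from the other 3 of its group by Dixon's test. Chance alone gives about 11.2 at the limit used. The total is thus near the number expected by chance. Of the 14, 10 were on control arrays and 5 on control array 3. How they fall over the arrays was not compared with chance, and no explanation was tested for them.

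For control array 3, its Dicer1 signal (1460571_at) was 2114 against 1141 to 1190 on the other controls, and the log2 difference of Dicer1 depends on it. Its Col15a1 signal was 6784 against 4128 to 4268, its Gaa signal 16830 against 11710 to 12150, and its Ifit1 signal 19830 against 25440 to 26350. Its score of the G1/S and DNA replication list, the mean log2 difference from the control mean, was -0.101 against 0.0281 to 0.0427. Control array 1 was the distant one for Nras (3558 against 2384 to 2507), Ptprv (4086 against 7669 to 8387) and Gadd45a (3427 against 6384 to 6722), control array 2 for the cholesterol synthesis list (-0.305 against 0.0863 to 0.121) and control array 4 for the senescence and secretory list (-0.233 against 0.0604 to 0.107). Among the knockouts, array 4 was distant for Ifit1 (42100 against 30100 to 31620) and for the senescence and secretory list (-0.191 against 0.0817 to 0.13), and array 1 for Fabp4 (1877 against 5952 to 6206) and Klf4 (9254 against 17320 to 18790). The senescence list was thus low on both arrays numbered 4.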

How the results depend on the processing

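The log2 difference of Hmga2 1450781_at kept its direction under every alternative, but its call, the only 1 in the unpaired fit, ended (0 probe sets higher) with no filter on low values, with median centring and without the mean-variance trend. Leaving out the filter adds probe sets to the adjustment; the other causes were not tested. The replicate block gave 10 probe sets higher and 3 lower, or 8 genes higher and 2 lower. Leaving out each array in turn, or each pair of arrays under the block, an alternative chosen after seeing the data, gave 0 to 45 probe sets higher, 0 to 35 lower, 0 to 34 genes higher and 0 to 24 lower, with the highest counts all under the block without pair 1. Gene lists past the threshold numbered 6 higher and 2 lower. They were 3 to 7 higher and 1 to 4 lower when arrays or pairs were left out, 1 lower with array weights, and 0 and 0 with an estimated correlation, alone or together with the replicate block. The block also changed the calls of 3 lists, the microRNA pathway, microRNA host and imprinted, and keratinocyte lists, and no other list's. With odd and even replicates as a block, likewise added after seeing the data, 1 probe set was higher, 0 lower, and 7 lists higher and 2 lower. A single left-out array leaves its partner unmatched. With whole pairs left out in the paired fit, the p53, contractile, let-7, lysosome, cholesterol, and host and imprinted lists kept their calls in every case. The interferon list lost its call without pair 1 (adjusted p = 0.336), the miR-21 list without pair 2 (0.211) and the microRNA pathway list without pair 1 (0.0769), pair 2 (0.0632) or pair 3 (0.0722). Lists not called in the paired fit passed there as well: miR-29 targets without pair 1 (0.0381) or pair 4 (0.0269), keratinocyte markers without pair 2 (0.0403) or pair 3 (0.0355), skeletal muscle markers and ribosomal proteins without pair 3 (0.0494 each), and G1/S without pair 4 (0.0298). Without Cxcl10 the interferon list stayed past the threshold.

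For the brighter Dicer1 probe set the log2 difference was -0.226 to 0.0572 over the left-out arrays, above 0 only without control 3. For the dimmer Dicer1 probe set it was -0.499 without control 4 and -0.0758 without control 3. Some lists that did not pass changed sign, most of them with a mean near 0. The preadipocyte list turned to 0.0156 with the larger pseudocount, 0.0273 with no filter, 0.0209 with the upper 40% of probe sets and 0.00238 with array weights. The endothelial list turned to -0.00255 with the larger pseudocount, -0.0338 with no filter and -0.0335 with array weights. Glycolysis turned to 0.00786 with no filter and 0.0152 with array weights, oxidative phosphorylation to 0.00305 with quantile normalization and 0.000696 with the mean over probe sets of a gene, and ribosomal proteins to 0.0107 with quantile normalization. The macrophage list turned to -0.111 with the upper 40%, where fewer members are tested, and array weights turned the unfolded protein response to -0.011 and the matrix list to 0.0153. Over left-out arrays or pairs the list means were -0.0376 to 0.117 for miR-29 targets, -0.0162 to 0.0977 for G2/M, -0.0455 to 0.107 for senescence, -0.0445 to 0.0132 for the antioxidant list, -0.0671 to 0.062 for the unfolded protein response, -0.0988 to 0.0586 for matrix, -0.0595 to 0.0571 for preadipocyte, -0.0471 to 0.0147 for brown fat, -0.0424 to 0.0242 for oxidative phosphorylation, -0.0285 to 0.0231 for glycolysis, -0.00134 to 0.0817 for apoptosis, -0.0424 to 0.0434 for ribosomal proteins, -0.145 to 0.137 for endothelial and -0.0547 to 0.157 for pericyte markers. Without a change of sign they were -0.154 (without control 1) to -0.0601 (without control 3) for adipocyte differentiation, 0.0611 (without control 1) to 0.152 for macrophage markers, -0.324 (without control 1) to -0.0607 (without knockout 1) for Schwann and neural markers, 0.133 to 0.347 for skeletal muscle markers and -0.0883 to -0.024 for G1/S. Genes called only over their own list in the paired fit moved too when an array was left out of the unpaired fit, its partner staying unmatched. Klf4 moved to 0.0693 without control 1, Dcn to -0.1 without control 4 and Fabp4 to 0.964 without knockout 1. Without control 1, Cdkn1c moved to -0.279 and Rian to -0.217. Ndn moved to -0.134 and Gsta4 to -0.347 without knockout 3, Mest to 0.263 without knockout 2, and Ndrg1 to -0.843 without knockout 1. For the sign changes the cause was not tested. No other named gene changed sign. The seed match alternatives were not run. Signal over background limits the dim probe sets, whose differences the pseudocount of 73.1 shrinks.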

Other observations

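The tests of the p53 and let-7 lists described here, and the comparison of the unpaired fit over splits that part every pair, were chosen after those results were seen, and the comparison of odd-numbered with even-numbered replicates was chosen after the 18S ribosomal RNA signals were seen.

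The largest count of probe sets past the threshold followed neither virus. Between the odd-numbered and the even-numbered replicates, with the group as a term of the limma fit, 879 probe sets passed the threshold, 655 higher and 224 lower in the odd-numbered ones, and 727 did so after median centring. This fit took all arrays as independent, although same-numbered control and knockout arrays deviated together. The replicate numbers, not the arrays, are the units of this split, so its p-values and counts overstate the evidence. Among the 25 genes with the smallest p were rapid-response genes: Ccn1, a matricellular growth factor (2.48-fold higher in the odd-numbered replicates, adjusted p = 0.000266), the phosphatase Dusp1 (2.35-fold, 0.000503), Nfkbiz (2.63-fold, 0.00357), Fos (2.49-fold, 0.00462) and Zfp36, which destabilises inflammatory messages (2.06-fold, 0.0084). Most of the 25 were genes of other kinds, and most of those were also higher in the odd-numbered replicates. Whether rapid-response genes were more frequent among the 25 than among all genes was not tested. The long noncoding RNA Meg3 read 12170 in the odd-numbered and 4124 in the even-numbered arrays (2.9-fold, 0.000319), and the mitochondrially encoded ND5 was 2.04-fold higher (0.00111). Fasn was 1.57-fold higher (0.00909), and the imprinted gene Mest lower (log2 difference -1.06, 0.00895), as were Dguok (-0.82) and Gfer (-0.58). The knockout effect on Hmga2 1450781_at was 1.39 on the log2 scale in the odd-numbered and 1.36 in the even-numbered replicates, with 0 probe sets past the threshold within either.

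Other splits of the 8 arrays bear on how far these counts can be read. The unpaired fit called 1 probe set, 4 of the 35 splits into 4 and 4 called as many, and the highest of the others called 946. That split sets odd against even replicates, so it points to a structure of the samples; with odd and even as a block the real count stayed at 1. For the 8 lists, 13 of the 35 splits put as many past the threshold, with 16 for the odd and even split, so chance cannot be excluded for either count over these splits. All but 8 of the 35 put both arrays of some pair on the same side, and so take in what pairs or odd and even replicates share. Among the 8 that part every pair, 1, the real one, called as many probe sets and 1 put as many lists past the threshold in the unpaired fit, with 0 probe sets and 6 lists in the highest of the others. In the paired fit, 1 of the 8, the real one, reached the 13 probe sets, and the highest of the others called 0. Likewise 1 of the 8 reached the 9 lists of that fit, with 8 lists in the highest other split. With 8 splits a share under 0.05 is out of reach. The other 7 exchange the control and knockout arrays of 1 or 2 pairs and so keep part of any real difference as noise.

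The p53 target list was higher in all 4 pairs, with a mean log2 difference of 0.20. The rise was not confined to dim probe sets, since members brighter than the median probe set had a mean of 0.216 (SE 0.0403 over members). That SE does not measure the spread between arrays, because the members vary together (estimated correlation 0.38). Over arrays, the exact two-sided permutation of the list mean gave p = 0.314, so noise between arrays is not excluded. This permutation does not use the pairing. Over the 4 pairs the SE of the mean difference was 0.044. A response to Cre recombinase or to its virus, rather than to the loss of Dicer, cannot be told apart from a Dicer effect, since 0 arrays are of Cre virus in cells without floxed Dicer. A p53 response to the loss of Dicer therefore stays open as a hypothesis next to Cre toxicity. Without control 1 the unpaired call was lost (0.0867). Both arrays numbered 1 were low on this list (-0.341 and -0.213 from the control mean), and leaving out control 1 alone leaves knockout 1 unmatched. Without both, the paired fit gave 0.224 and kept its call with the preset correlation. With all pairs, the list did not pass in the paired fit by camera with an estimated correlation (adjusted p = 0.286) or by fry (adjusted p = 0.0884).

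The let-7 target list was higher in all 4 pairs, with a mean of 0.13. How far its rise rests on Hmga2 and Nras stays open. The other members had a mean of 0.0564 (SE 0.0526 over members), but leaving out 2 members picked for their rise lowers the mean in any case. Of the others, 4 passed as higher adjusted over the list alone in the paired fit. Whether the let-7 list rose more than microRNA targets in general stays open, because it exceeded the miR-29 list by 0.0759 (SE 0.0752 over members) and differed from the miR-21 list by -0.00912 (SE 0.0906). Loss of mature let-7 in the knockout is a hypothesis that mRNA arrays alone do not settle; mature microRNAs were not analysed here.

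For the split between odd and even replicates, array scaling is argued against as the cause, since 842 probe sets still differed after quantile normalization. A difference in handling, such as the time since the last change of medium, is a candidate explanation. A list of immediate-early genes written before this test, without those already seen among the top genes, was higher in the odd-numbered replicates by 0.365 on the log2 scale (SE 0.117 over 24 members, 16 of them above 0 and 6 past the threshold). Genes of this kind had already been seen in the same split, so the list is no independent support for that explanation. Its SE over members does not measure the spread between replicate numbers. Different litters or culture batches stay open, since the labels do not say what a replicate number stands for, and no biological explanation was tested.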
